A study of Rattus norvegicus with 9 samples.

How the data were processed

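Total RNA from samples labelled as cerebral cortices, of 5 rats after cardiac arrest (CA) and 4 sham-operated rats, was assayed on 9 Agilent arrays, 1 per rat, with Cy3 label from 0.2 µg of RNA. Per the labels, CA was induced in rats under pentobarbital (30 mg/kg) with a 10 s current of 6 V at 50 Hz across the chest, chest compressions began after 8 min, and the rats were kept for 2 h after circulation returned. Groups were taken from the labels, which name CA rats and sham-operated blank controls.

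The authors deposited 1 scanner file per array, with values as fluorescence intensity, made with Agilent Feature Extraction 10.7.1.1. Per the file headers, the processed intensity is subtracted for background and detrended within the array, dim spots hold a surrogate, and no step normalizes between arrays. The files also hold other columns deposited by the authors, which are 0 or 1 marks for spots that are well above background, saturated or outliers. A further deposited table of values gives a single value per probe and array on a log2 scale, judged from its values, and its columns share nearly the same quartiles, with a median of 5.87 in each, as quantile normalization gives. The method behind that table is not given in the sources used here, and it served only as an alternative.

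Control spots (1131 positive and 308 negative) were left out of the tests, as were spots with a mark for a non-uniform or population outlier. The log2 processed signals of a probe's remaining spots (1, 3 or 10 spots) were averaged, and each array's 75th percentile over all sample probes was subtracted. A probe was tested if it was well above background on at least 4 of the 9 arrays, which kept 28976 of 40351 probes, and 16898 were well above background on all arrays. The filter, the normalization, the model without covariates and the thresholds were chosen before the data were examined. The plan to use 1 probe per gene, to count mRNAs and lncRNAs and to test gene lists with camera and fry could not be carried out, because the files give no gene names or RNA classes and no probe table was given. Every probe was therefore its own feature, and catalogue and custom probe names took the place of RNA classes, a choice made after the data were seen.

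CA was compared with sham in R 4.3.3 by limma 3.58.1 (lmFit and eBayes, 2-sided, Benjamini-Hochberg over all tested probes, adjusted p under 0.05). Tables were handled with the data.table package (version 1.17.8). The model with scan day as a block was among the alternatives fixed beforehand. It is reported beside the model without a block because the arrays separated by day. The earlier day holds 3 CA and 1 sham array, and the later day 2 CA and 3 sham arrays. Slides were also used as a block: 1 slide holds the 5 arrays of the later day, another holds 3 arrays of the earlier day, and the last holds CA replicate 5 alone. Within-day differences are the CA mean minus the sham mean on that day, and the 2-fold limit on both days is a criterion without a test, chosen after the data were seen. Labels were reassigned in all 40 ways that keep the number of CA arrays per day, and 100 of the 126 splits of the 9 arrays into 5 and 4 were drawn with a fixed seed. The pair of probes with the smallest unadjusted p in each direction is named, without regard to their values otherwise.

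The model was tested on simulated data with the means, day shifts and residual spread of 28953 probes and 200 changed probes. Without a block, 0%, 28.4% and 40.9% of changes of 1, 2 and 3 log2 units were called, with 0 false calls. With scan day as a block, 17.9%, 59.7% and 83.3% were called, with 6 false calls.

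To look for other tissues, probe sequences of 60 bases were translated and searched with Biostrings 2.70.1 for exact matches of at least 8 residues to protein segments. The segments were written from general knowledge, not from a sequence database, and after the arrays had been seen to separate by day. They came in 6 lists: 10 of striated muscle, 12 of brain, 2 of red cells, 3 of proteins shared by all cells, 9 of stress responses and 6 of inflammatory mediators. Tested probes were found for 7, 6, 2, 3, 5 and 1 of these, with 13, 8, 5, 188, 13 and 1 probes. Segments were written in 2 rounds, the second after the first had been matched, and 5 of the muscle segments had been recognised in probe sequences beforehand. The list names rest on these matches and not on the array's annotation, and no single probe is given a gene name on this basis. For differences between the days, signals under the 5th percentile of an array's probes well above background were also held at that limit. This makes a difference a lower bound in size where only the day with the lower signal falls under the limit. A list's shift is the median over its segments of the CA minus sham difference, with each day weighted by the product of its CA and sham array numbers over their sum, and with an exact 2-sided p over the 40 reassignments and Benjamini-Hochberg over the 6 lists.

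Alternatives were normexp background correction (offset 50) on raw signals, the 75th percentile over probes detected on all arrays, quantile normalization, the deposited value table, no filter, a filter for all 9 arrays, eBayes with trend and robust, array weights, slide, scan day and replicate number as a block, an unadjusted p under 0.05 with a fold of at least 2, and each array left out in turn. Each scan day alone, array weights over probes without a missing value, and outlier spots kept were added after the data were seen. limma fits array weights by a different method when values are missing, as they were for 23 tested probes, so both versions are given. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.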

Results

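RNA abundance was measured in samples labelled as cerebral cortices of male Wistar rats, with 1-colour Agilent arrays that carry probes for mRNAs and long noncoding RNAs (lncRNAs). Per the labels, 5 rats underwent cardiac arrest (CA) by electrically induced ventricular fibrillation and were kept for 2 h after the return of spontaneous circulation, and 4 sham-operated rats served as controls. Each rat gave 1 array, so n was 5 for CA and 4 for sham in comparisons over all arrays. Each array held 62850 spots and 40351 distinct sample probes, of which 30367 carried catalogue names and 9984 carried custom-design names. The files pair no probe with a gene, a transcript or an RNA class, so probes are given by their own identifiers, and catalogue and custom probes are counted separately instead of mRNAs and lncRNAs.

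The share of probes well above background was 73.4%, 71.3%, 61.8%, 49.8% and 55.2% on the arrays of CA replicates 1 to 5. It was 58.6%, 72.7%, 70.7% and 70.3% on the arrays of sham replicates 1 to 4. No sample spot was saturated. The arrays were scanned on 2 days: CA replicates 3, 4 and 5 and sham replicate 1 on the earlier day, and CA replicates 1 and 2 and sham replicates 2, 3 and 4 on the later day, so within-day differences rest on 3 CA and 1 sham array and on 2 CA and 3 sham arrays. Probes encoding heart muscle protein segments lay far higher, and most brain segments lower, on the 4 arrays of the earlier day, sham and CA alike, so values pooled over the days mix arrays that differ in this way. The number of arrays, and the single sham array of the earlier day, limit the precision of every comparison.

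The comparison of CA with sham asks which lncRNAs and mRNAs differ 2 h after resuscitation in what the labels give as cerebral cortex for all 9 arrays. The probe with the smallest p among those higher after CA was A_64_P123603. Its log2 signal relative to the array's 75th percentile was 3.64 ± 0.44 (SD, n = 5) after CA and 0.87 ± 0.43 (SD, n = 4) in sham, a log2 difference of 2.78 with a standard error of 0.318. It was higher by 3.11 on the earlier scan day and by 2.46 on the later one. The custom probe CUST_47279_PI429483654 had 2.03 ± 0.46 (SD, n = 5) after CA and -0.38 ± 0.29 (SD, n = 4) in sham, a difference of 2.40, with 2.70 and 2.21 on the earlier and later days. All 5 CA arrays lay above every sham array for both probes, and neither passed correction over all probes in limma without a batch term (adjusted p = 0.290 for each). The sequences of these 2 probes overlap over 51 bases with 4 mismatches, so their signals are not independent.

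Among probes with lower signal after CA, A_64_P003254 had the smallest p, with -4.52 ± 0.70 (SD, n = 5) after CA and -1.98 ± 0.41 (SD, n = 4) in sham. Its log2 difference was -2.54, with -2.29 and -2.24 on the earlier and later days, and limma gave an adjusted p of 0.513. All its CA values of the earlier day, -5.54 to -4.03, lay under those arrays' detection limits of -2.99 to -1.68, so the size of -2.29 is uncertain. A_64_P121981 had -2.78 ± 0.28 (SD, n = 5) after CA and -1.59 ± 0.20 (SD, n = 4) in sham, a difference of -1.19, with -0.87 and -1.48 on the earlier and later days. Its adjusted p in limma was 0.799. All 5 CA arrays lay below every sham array for both of these probes. Both were dim, well above background on 6 and 7 of the 9 arrays, and with normexp background correction their differences shrank to -0.66 and -0.40.

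**Figure D1:**
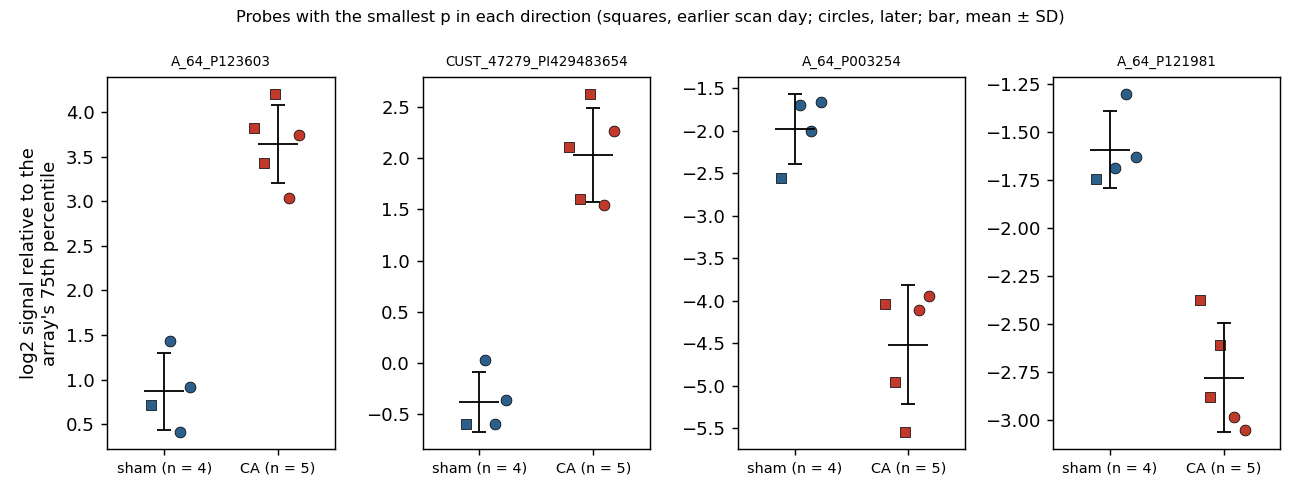
Log2 signal relative to the array's 75th percentile for the pair of probes with the smallest p in each direction, in sham (n = 4) and CA (n = 5) arrays, with squares for the earlier and circles for the later scan day and bars for mean ± SD. The groups do not overlap for any of the 4 probes, and none of the 4 passed correction (adjusted p 0.290, 0.290, 0.513 and 0.799).

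Of 28976 probes tested, 23216 catalogue and 5760 custom, limma called 0 catalogue and 0 custom probes higher and 0 catalogue and 0 custom probes lower after CA at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 749 probes, 504 of them higher after CA. Over the 100 splits drawn, the median was 248 such probes. At least 749 were given by 30 of the 100, the real one included, so chance was not excluded. The counts of probes at an adjusted p under 0.05 and 2-fold or more were 0 in both classes as well. With weights per array, fixed as an alternative beforehand, the counts were also 0. With the weights fitted over the probes with no missing value, a version added after the data were seen, 4 catalogue and 2 custom probes were called higher and 2 catalogue probes lower.

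With the scan day as a block, 3 probes rose after CA and 0 fell, all 3 of them catalogue probes. Their log2 changes were 3.11, 5.99 and 2.12, with adjusted p of 0.0221, 0.0402 and 0.0402 from limma. For each of the 3, all 3 CA arrays of the earlier day lay above its sham array and both CA arrays of the later day lay above its 3 sham arrays. An unadjusted p under 0.05 was reached by 1420 probes in this model. Other assignments of the labels within scan days that kept CA replicate 3 in the CA group gave 200 to 1290. Those that set it as the earlier-day sham array gave 1969 to 3422, so the real count was not the highest. The count of 3 fell to 0 without CA replicate 1, CA replicate 2 or any 1 of sham replicates 2, 3 and 4; it was 1 without CA replicate 5 and 6 without CA replicate 3. Over the processing alternatives it ranged from 0 to 73.

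Separate comparisons within each scan day gave 252 probes that were at least 2-fold higher after CA on both days, 219 catalogue and 33 custom, and 44 that were at least 2-fold lower on both days, 40 catalogue and 4 custom. Another 127 probes differed at least 2-fold in opposite directions. Of the 252 probes, 33 were at least 4-fold higher on both days, and of the 44, 3 were at least 4-fold lower. The 252 probes were dimmer than the tested probes as a whole, with a median level of -2.64 against -1.11, and 158 of them still met the 2-fold limit on both days without CA replicate 3. The count was 59 with normexp background correction, 94 over probes well above background on all 9 arrays and 98 in the deposited log2 values, where 11 of 40 assignments of the labels gave as many. Over the 40 possible assignments of the CA and sham labels within scan days, the next highest count of higher probes was 164. At least 44 lower probes were given by 14 assignments, the real one included. Those that set CA replicate 3 as the earlier-day sham array gave 5 to 26 higher and 76 to 254 lower probes. The others besides the real one reached at most 164 and 71. The within-day differences of the 2 days had a Pearson correlation of 0.119 across probes, which are not independent replicates, and 2 of the 40 assignments gave a correlation at least as high.

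**Figure D2:**
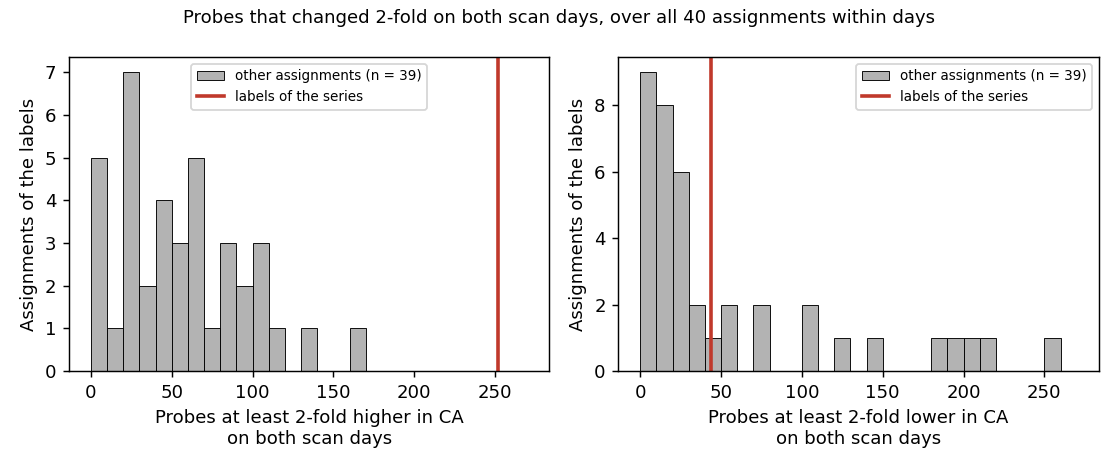
Number of probes that differed at least 2-fold in the same direction on both scan days, for probes higher (left) and lower (right) after CA, over all 40 assignments of the labels within scan days. Grey bars count the other 39 assignments and the red line marks the labels of the series. It lies at 252 higher probes, where no other assignment exceeded 164, and at 44 lower probes. For lower probes, assignments with CA replicate 3 as the earlier-day sham array reached 254, and the others reached 71.

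The array carried named control probes for glycolytic enzymes. The 3' GAPDH control, glyceraldehyde-3-phosphate dehydrogenase of glycolysis, had a log2 signal of 7.41 ± 1.14 (SD, n = 5) after CA and 6.80 ± 0.81 (SD, n = 4) in sham. Under this scaling, CA minus sham was 0.22 on the earlier day and -0.23 on the later day, where the SD was 0.21 over the CA arrays and 0.07 over the sham arrays. The earlier minus the later day was 1.86. The 3' control of PGK1, the glycolytic phosphoglycerate kinase, had 3.37 ± 0.83 (SD, n = 5) after CA and 2.73 ± 0.63 (SD, n = 4) in sham, with 0.30 and 0.07 within the earlier and later days. The later-day SDs were 0.37 for CA and 0.19 for sham, and the earlier minus later day difference was 1.43. The single sham array of the earlier day allows no SD there.

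The arrays separated by scan day and not by group. The first principal component held 75.7% of the variance over tested probes and parted the days. Arrays of the later day had Spearman correlations of 0.962 to 0.984 with each other across probes. Those of the earlier day without CA replicate 3 had 0.954 to 0.970, and pairs across the days had 0.690 to 0.720. CA replicate 3 had 0.840 to 0.873 with the other earlier arrays and 0.601 to 0.623 with the later ones. With the group in the model, 7757 probes were higher and 7581 lower on the earlier day, which is 52.9% of those tested, and 2724 probes differed at least 8-fold. Probes whose sequences encode 7 segments from a list of striated muscle proteins, all of them made in heart muscle, lay higher on the earlier day by a median over segments of at least 10.32 (log2), in CA and sham arrays alike. This holds signals under an array's detection limit at that limit, since on the later day 47 of 65 values of these probes were well above background. The segments recognised in probe sequences beforehand lay higher by 9.16 to 12.20, and the others, not recognised beforehand, by 5.97 and 7.43. Over the 6 brain protein segments found, the median difference computed in this way was -1.94, with a range of -8.90 to 2.79, and 25 of 32 values on the earlier day were well above background.

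**Figure D3:**
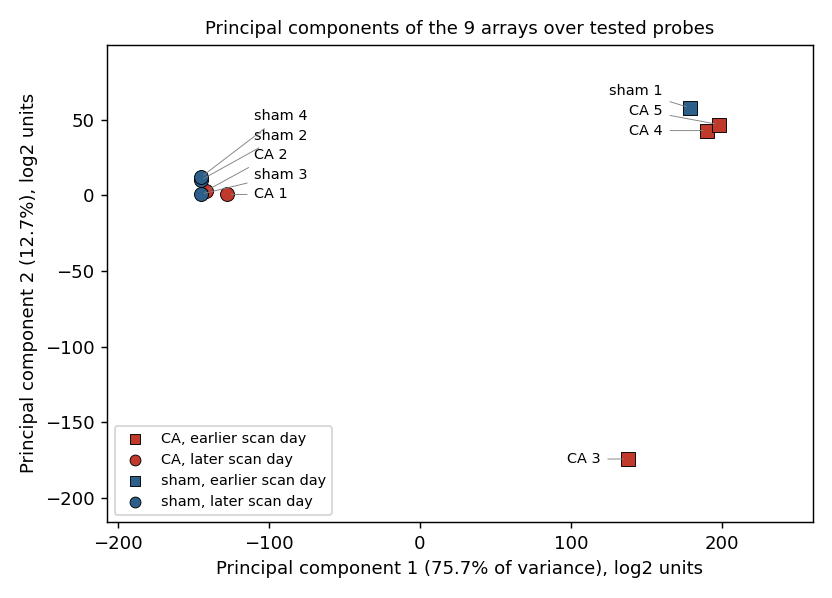
The 9 arrays on the first principal components of log2 signal relative to the array's 75th percentile (75.7% and 12.7% of the variance), with colour for the group and shape for the scan day. The first component separates the 4 arrays of the earlier day, sham replicate 1 among them, from the 5 of the later day, and the second separates CA replicate 3 from the other 8.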

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

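All tests of this part were chosen after the results they concern had been seen. The most distant array of each group was compared with the rest of its group on several measures, and 4 of 24 such comparisons were flagged. Chance gives about 1 in 20 only for independent measures. These are not, since the named probes were picked by p and several measures follow the scan day. Sham replicate 1, the only sham array of the earlier scan day, had 58.6% of probes well above background, against 70.3% to 72.7% on the other sham arrays. It also had a median log2 signal of 7.09 over the striated muscle segments, against -3.52 to -2.79, and of 0.17 over the brain segments, against 2.74 to 2.95. CA replicate 3 had a mean negative control signal of 75.5, against 25.3 to 39.4 on the other CA arrays.

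The first pattern weighed is the separation of the arrays by scan day, which was shared by CA and sham arrays and shifted 52.9% of tested probes. A difference of scanning or hybridisation alone was argued against by the 35 E1A, ERCC and ETG control probes, which shifted between the days by -0.62 to 2.72 on the scale of the sample probes and by -1.85 to 1.48 in raw log2 signal (at most 0.149 for the brightest 3, down to -2.60 without CA replicate 3), while 1150 sample probes were at least 8-fold (3 log2) higher and 1574 lower on the earlier day. Cortex with a minor share of other RNA was argued against by the brain segments, whose median shift was -2.14 (-1.94 with signals held at the detection limit): the brightest pair, at levels of 6.55 and 6.50 on the later day, differed by -8.90 and -7.26 as lower bounds in size, although 1 of the 6, a match of 9 residues, went up by 2.79. A candidate explanation is striated muscle RNA, with heart as the candidate tissue, in place of most cortex RNA on the 4 earlier arrays. The 5 heart muscle segments recognised beforehand lay higher there by at least 9.16 to 12.20, at levels up to 8.0. The pair not recognised beforehand, detected on all arrays, lay higher by a median of 6.73. Of this pair, 1 (7.43) belongs to a protein that brain also makes, and the other lay 6.03 higher. The brain median of -2.14 narrowly passed the 2 log2 set for this explanation, a limit set after the data were seen. With signals held at the detection limit it was -1.94, a bound in size that does not reach 2 log2, so this median alone cannot decide. Segments specific to skeletal muscle were not searched, the labels name cerebral cortices for all 9 samples, and no biological explanation was tested because the design gives no group that follows the days.

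The second pattern is the set of 252 probes at least 2-fold higher after CA on both days. Chance was argued against by the 40 assignments of labels within days, of which only the real one (1 of 40) gave as many. The highest other gave 164. The same held with normexp (59 against 10) and without CA replicate 3 (166 against 73). It did not hold in the deposited value table (98, with 11 of 40 as many). Because 1 of 40 is the smallest share possible and the criterion was chosen after the data were seen, chance was not excluded. Raised background on CA replicate 3 as the whole cause was argued against by 62.7% of the probes that met the limit without it. Of the 252 probes, 30 exceeded the highest red cell segment probe on both days, where other assignments gave at most 5. Of these 30, 17 were well above background on all arrays. This argues against more blood in the CA samples as the whole cause only if blood raises no transcript more than those of red cells. That condition was not tested. For the rest of the 252 probes, raised background on CA replicate 3 and more blood both stay open. A response to arrest and resuscitation stays open as a hypothesis, and so do differences in dissection between the groups, which were not tested. If the earlier arrays held mostly muscle RNA, the limit on both days asked for the same change in different tissues.

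The third pattern is the signal of CA replicate 3, which lay above CA replicates 4 and 5 by a median of 2.87 (log2) in the dimmest eighth of probes and by 0.44 in the brightest. A different RNA composition alone was argued against by the 29 dimmest of these control probes, which also lay higher, by a median of 3.33 (1.35 to 5.53). An additive background on this array may account for the dim probes, since the brightest 3 controls differed by at most 0.208. It does not account for bright sample RNA. The raw 3' GAPDH control was 15.74, against 15.18 and 15.16 on CA replicates 4 and 5. The raw 3' PGK1 control was 11.68, against 10.59 and 10.99. These values argue against background as the whole cause. No biological explanation was tested, because no group of the design sets this array apart from the other CA arrays.

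Among 100 of the 126 splits of the 9 arrays, 100 of 100 called at least the 0 probes of the real split without a block, as any split must, so this count says nothing about chance. At an unadjusted p under 0.05, 30 of the 100 gave at least the 749 probes of the real split. The highest other split called 16539 probes; it sets all 4 earlier arrays against the later ones, and the 4 splits that put all 4 earlier arrays in the larger group called a median of 5459, which points to the structure by scan day. With scan day as a block, the 3 calls were reached by 1 of 40 assignments within days, the real one. The highest other gave 1. This share is the smallest possible, and leaving out CA replicate 1 alone lowered the calls to 0, so chance was not excluded. Other assignments also gave up to 3422 probes at an unadjusted p under 0.05, against 1420 for the real one. All of those above 1420 set CA replicate 3, the array with the high negative control signal, as the earlier-day sham. The highest of the rest gave 1290.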

How the results depend on the processing

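The counts of catalogue and custom probes called higher and lower after CA stayed at 0 under every alternative run except these. Catalogue probes called higher, and those at 2-fold or more, were 3 and 3 with scan day as a block and 1 and 1 with slide as a block. Array weights over the probes with no missing value, added after the data were seen, gave 4 catalogue and 2 custom probes higher, 2 catalogue lower, and 6 catalogue and 2 custom at 2-fold or more, while array weights over all tested probes gave 0. An unadjusted p under 0.05 with a fold of at least 2 gave 301 catalogue probes higher, 94 lower, 58 custom higher and 27 lower. Without a block, leaving out any 1 array kept every count at 0. The replicate number as a block gave 0 as well, and the deviations of arrays with the same number correlated by -0.85, 0.82, -0.29 and -0.73 across probes. These follow the scan day, which only the replicates numbered 2 share, and so tell nothing about pairing; the labels give separate rats. The 4 named probes kept their direction in every alternative in which they were tested, but normexp shrank A_64_P003254 from -2.54 to -0.66 and A_64_P121981 from -1.19 to -0.40; 1 call was gained in all, A_64_P003254 with array weights over probes with no missing value (-2.94, adjusted p 0.0346; adjusted p 0.0346 to 1.000 over its alternatives).

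All alternatives of the counts with scan day as a block and of the counts on both days were added after the data were seen. With scan day as a block (3 higher, 0 lower), normexp gave 46 and 5, the 75th percentile over probes detected on all arrays 1 higher, quantile normalization 1, the deposited values gave 0, no filter 0, the filter for all 9 arrays 65 and 4, trend and robust 43 and 1, array weights 49 and 12, array weights over probes with no missing value 73 and 20, slide as a block 1, the later day alone 0, the earlier day alone 0, and the later day alone with outlier spots kept 4 and 6. Leaving out 1 array gave 0 to 6 higher and 0 to 2 lower, except sham replicate 1, without which the earlier day has no sham. On both days (252 higher, 44 lower), normexp gave 59 and 3, quantile normalization 163 and 75, the deposited values gave 98 and 68, no filter 524 higher, and the filter for all 9 arrays 94 and 8. Leaving out 1 array gave 166 to 337 higher, lowest without CA replicate 3, and 35 to 83 lower, highest without CA replicate 1. The causes were not tested, apart from the filters, which change the probes tested, and the left-out arrays. The red cell list was above 0 in all 14 settings, from 1.54 to 2.58, and had an unadjusted exact p under 0.05 in the 12 that can reach it; without CA replicate 1 or 2 the p of 0.0625 is the smallest possible and tells nothing. The stress response list had such a p in 5 of those 12. Camera, fry and 1 probe per gene were not run, for want of gene names. Dim probes limit these counts, since those higher on both days had a median level of -2.64.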

Other observations

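All tests of this part were chosen after the data were seen. Probes encoding segments of red cell proteins lay higher after CA on both scan days, by 2.58 on the earlier and 1.53 on the later day (log2), and by 1.94 with the days weighted together. On the later day CA replicate 1 lay 2.57 above the sham mean and CA replicate 2 only 0.49, so the later-day difference rests mostly on CA replicate 1, without which the weighted value was 1.54. All 5 of the list's probes were at least 2-fold higher on both days. The shift was the highest of the 40 assignments of labels within days (exact 2-sided p = 0.025, the smallest they can give, highest other 1.71, 1 of 40 as far). After correction over the 6 lists the adjusted p was 0.1, so the list did not pass and chance was not excluded. With this smallest p, a list could pass only if other lists reached it too, so not passing says little. That CA samples held more red cells or blood is a hypothesis that these values may fit, and they do not separate it from other sources of these transcripts.

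Probes encoding segments of stress response proteins had a weighted median difference of 0.43 between CA and sham, with 0.55 on the earlier and 0.36 on the later day, and 2 of 40 assignments moved the list as far (exact p = 0.05, adjusted 0.1; highest other 0.49), so chance was not excluded. It was 0.94 (exact p = 0.025) with matches of at least 12 residues and 0.75 (exact p = 0.0556) without the scan day block. The value of 0.94 is that of a single probe, higher by 1.82 on the earlier and 0.39 on the later day. Within the list, 3 of the 5 segments were higher on both days, with weighted differences of 1.66, 1.57 and 0.43, and 2 were lower on both, with -0.25 and -0.22, both of them matches of 8 residues that the longer limit leaves out. The single tested probe of the inflammatory mediator list, a match of 19 residues, was higher by 3.94 on the earlier and 0.93 on the later day (exact p = 0.075, adjusted 0.112). The later-day difference rests on CA replicate 1 (-2.06), since CA replicate 2 (-4.31) lay within the sham values of -4.61 to -3.66. On the earlier day the single sham value of -3.89 lay under that array's detection limit of -3.15, so the size of 3.94 is uncertain. The striated muscle list differed by 0.34 between CA and sham (exact p = 0.05, adjusted 0.1), with 0.35 on the earlier and -0.03 on the later day. The brain list differed by -0.37 (exact p = 0.15, adjusted 0.18), and the list of proteins shared by all cells by 0.09 (exact p = 0.575, adjusted 0.575).

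The signal of the 3' GAPDH control exceeded that of the 5' control by 1.88 to 2.12 (log2) on the later day and by 1.44 to 1.61 on the earlier day.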
